A study of Sus scrofa with 125 samples.

How the data were processed

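The deposited files are the per-array outputs of Feature Extraction, with 1 intensity per spot in the Cy3 channel; per the file headers, 117 arrays were read with version 10.7.3.1 and 8 arrays, all of scan day 3, with version 11.5.1.1. The deposited intensity is taken as the processed signal of the authors' files, background-treated by that software. Per the labels' protocols, 50 to 100 mg of scraping went into a phenol-based RNA extraction with column clean-up, and 200 ng of total RNA were amplified, of which 600 ng of labelled cRNA were hybridized. Per the submitters' processing notes, R 3.0.2 and limma (version not given) were used, without a stated role. No sequence reads and no raw scan images were used here.

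Each array has 45122 spots, of which 43603 distinct probes are not controls. Of 7111 probes with a RefSeq accession, 6686 were matched to 3020 genes, 58 of them LOC symbols, which are counted and not named. The other 36917 probes carry no gene here and are counted as features without a name. For a gene with several probes the one with the highest mean over all arrays was used. Among 1565 such genes, 465 had all probes correlating above 0.8 with the used probe, and 562 had a probe under 0.5. Among the named genes these were ACACB, BPIFB1, C4BPA, CCND3, CLN3, CREB3L4, CSNK2B, DEFB1, FCGR2B, HAPLN1, HNF4A, IDH3B, KCNA5, NLN, PDE4A, RSC1A1, SLC11A1, TAP2, TMEM57 and TP23.

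Log2 signals were set to a common 75th percentile per array, taken over probes well above background on all arrays of the fit. Probes had to be well above background on at least as many arrays as the smallest arm holds. Each tissue and day was fitted with limma 3.58.1 (statmod 1.5.0, R 4.3.3; the package data.table was at version 1.17.8) with terms for arm and sex, and with litter as a random block through duplicateCorrelation, because the additive was given per litter. Control age and age-dependence came from 1 fit per tissue with all 6 arms. The estimated litter correlations of these fits ran from -0.104 to 0.356. A feature passed at an adjusted p (Benjamini-Hochberg) under 0.05. No 2 arms of the same tissue and day share a slide, so slide could only be a random block. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.

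Before the data were examined, 32 gene lists (pathways, cell types, label checks) were fixed, of which 22 to 24 with at least 5 members were tested per comparison with camera at its preset correlation of 0.01. Each list test was repeated with an estimated correlation between genes, with fry and with scan day as a block, and members were also adjusted over the list alone. The groups, the main test and most alternatives were also set before the data were examined. The named genes are the 10 with the largest change in each direction among those that passed, or all if fewer, for additive and age, and the 5 largest for route and age-dependence. Members of the fixed lists that passed are counted, with examples. Where none passed, the 5 smallest p are given as values.

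Groups follow the titles. In most groups the characteristics fields for treatment or route contradict the titles on at least 1 array. The source names and sows go with the titles, so the characteristics served only as an alternative. The design text places neonatal piglets at day 31 alone, whereas titles give them at day 1 as well. Controls titled maternal are all male and controls titled neonatal all female. For 1 day 31 colon control the animal number differs from that of the same sow in the other tissues. Tissue and age were checked on every array with 3000 variable features. Sex was checked with a signature of 5 probes higher in labelled males and 3 higher in labelled females. These probes were chosen on the other 2 tissues, without slides 6 and 7, and not by chromosome. The Y-linked SRY was well above background on 4 male and 6 female arrays and did not tell the sexes apart. In all, 15 arrays were in doubt and 110 were not. Own-label correlations were at least 0.823 off slides 6 and 7 and from 0.574 to 0.847 on them. No 2 arrays were identical.

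The alternatives were quantile normalization, normexp background correction with offset 50, filters on dim probes, single probes, no replicate block, litter means, no sex term, slide as block, array weights, other choices of arms and controls, and leaving out each array in turn. The planned mean spot signal for normexp is not in the files, so the median spot signal took its place. A count moved if it changed by more than 1.5 times or to or from 0. Arrays were also split 100 times into groups of the same sizes. The fit and the list test were tried on simulated data with 200 changed features per comparison. They recovered 4% to 48% of changes of 2-fold and 59% to 84% of 4-fold, with 2.11% to 11.3% false among the calls. They called 0 of 20 unchanged lists. The simulation left out scaling, the filter on dim probes, correlation between genes and slide differences. Its false calls can therefore understate those in the real data. A simulated litter correlation of 0.3 was estimated at 0.299 to 0.32.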

Results

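Gene expression was measured in mucosal scrapings of the jejunum, ileum and colon of piglets from 34 sows, on single-colour arrays with 1 scraping per array. Per the titles, each tissue went with a single feed additive: medium-chain fatty acids (MCFA) with the jejunum, β-glucans (cell wall polysaccharides of yeasts, fungi and cereals) with the ileum, and galacto-oligosaccharides (GOS, short galactose chains that pigs do not digest) with the colon. The additive was given to the newborn piglets themselves (neonatal route) or to the sow in her lactation feed (maternal route), beside untreated controls. Scrapings were taken at day 1 and at day 31, which was 3 days after weaning. At day 1 the control, neonatal and maternal arms held 8, 8 and 7 arrays in the jejunum, 8, 6 and 7 in the ileum and 6, 8 and 5 in the colon. At day 31 they held 8, 7 and 6 arrays in the jejunum, 8, 6 and 7 in the ileum and 8, 8 and 4 in the colon. Control and neonatal arms had up to 2 piglets from each of 3 or 4 litters, and maternal arms had 1 piglet per litter. Per the labels, the MCFA and GOS maternal arms held males only and the controls both sexes, so the sex term there rests on the other arms. Between 29.8% and 85.32% of the spots (median 59.74%) lay well above background, no spot was saturated, and the number of arrays limits the precision of every value. The comparisons ask how the mucosa of untreated piglets differed between both ages, what each additive did at each age, and whether the route mattered. Changes are log2 fold changes ± SE, and a gene rose or fell only where its adjusted p was under 0.05.

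FABP2, the fatty acid carrier of small-intestinal absorptive cells, and CA4, a carbonic anhydrase of colonocytes, checked the tissue labels. On slides 6 and 7 all 10 arrays had profiles that fitted another tissue or age better than their own label. On the 5 arrays labelled day 1 colon GOS maternal, the mean normalised log2 signal of FABP2 was 4.19 against -5.43 on the day 1 colon controls, and that of CA4 was -1.05 against 4.92. CCL25, a chemokine of the small intestine, stood at 2.30 against -5.95 on the same arrays. The 4 day 31 jejunum controls on slide 6 (replicates 1 to 4) had a mean FABP2 signal of -3.85, against 4.33 for the 4 on other slides, and their CA4 signal was 4.09 against -1.16. The remaining array on these slides was day 1 ileum β-glucan maternal replicate 7. Elsewhere 1 array, day 31 jejunum MCFA maternal replicate 2, had a profile closer to day 31 ileum. The sex signature went against the labelled sex on 9 arrays, of which 5 were on slides 6 and 7. Groups were kept as labelled. Results whose compared arms hold arrays of slides 6 and 7 are also given without them, an alternative chosen after the data were seen.

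**Figure D1:**
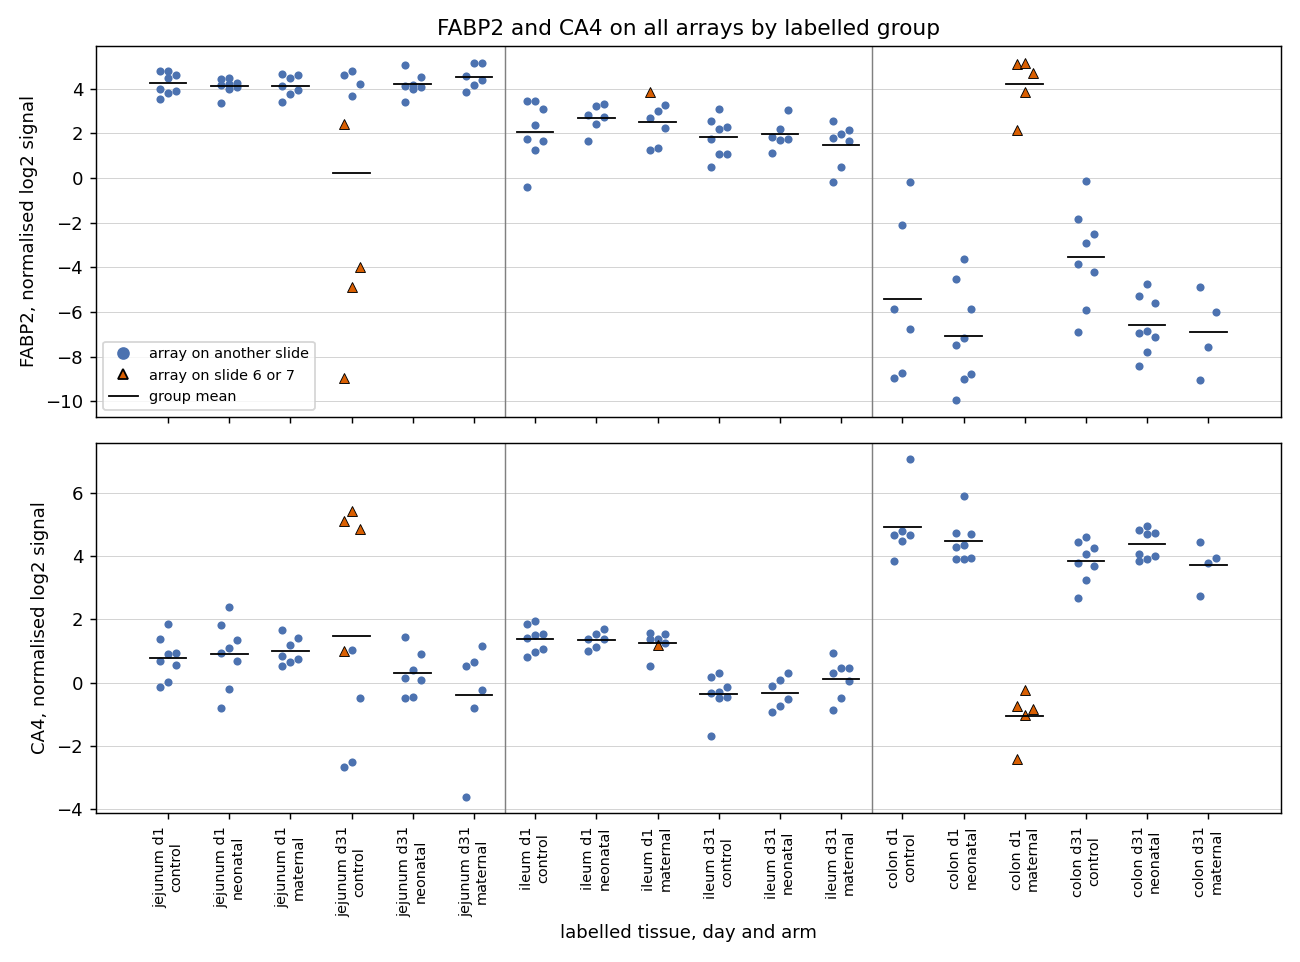
Normalised log2 signal of FABP2 (upper panel) and CA4 (lower panel) on each array, by labelled tissue, day and arm, with group means as bars and the 10 arrays of slides 6 and 7 as triangles. The 5 arrays labelled day 1 colon GOS maternal have a mean FABP2 signal of 4.19, near the small-intestinal groups, while the other day 1 colon arrays lie far lower.

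In the jejunum of control piglets, interferon-response, lymphocyte and cytokine genes were higher at day 31 than at day 1, and enteroendocrine genes were lower. The interferon-response, T and NK cell and cytokine lists alone held with an estimated correlation between genes. Without slides 6 and 7 (4 arrays at day 31 against 8 at day 1), the largest rises were OASL (8.97 ± 0.64), an interferon-induced antiviral gene, and the interferon-γ-induced chemokines CXCL11 (7.27 ± 0.73) and CXCL9 (6.45 ± 0.81). CCR7, the receptor that guides lymphocytes into lymphoid tissue, rose by 6.70 ± 0.69. They were followed by FABP6 (6.49 ± 1.67), the bile acid carrier of the distal small intestine, and VPREB1 (6.40 ± 0.80), a surrogate light chain of pre-B cells. The B-cell antigen MS4A1 (6.20 ± 1.00), IFIT1 (6.05 ± 0.56) and UBD (5.98 ± 0.82) also rose. So did GZMK, a granzyme that was not well above background on any day 1 array and at least 19.1-fold higher at day 31. On the scale of all arrays, MS4A1 and the B-cell gene CD79A ran from -7.36 to -1.85 and from -7.13 to -1.71 on these 4 day 31 controls. Their means were -8.15 and -6.44 in the day 31 neonatal MCFA arm and -7.51 and -5.69 in the maternal arm. Single arrays of the maternal arm ran from -10.37 to -0.44 and from -7.78 to -0.58. That arm includes replicate 2, whose profile was closer to day 31 ileum. Day 1 controls had means of -10.09 and -9.47. The size of the B-cell rise thus rests on few and unlike control arrays. The largest falls were MMP20 (-7.59 ± 0.54), coagulation factor F10 (at least 119-fold), the mucosal lipid-binding protein BPIFB1 (at least 32.6-fold), the plasma protein precursor AMBP (at least 24.7-fold) and prothrombin F2 (-6.35 ± 0.49). EPOR, INS and TUBB1 fell at least 18.1-fold, 16.5-fold and 14.4-fold, and ITIH4 and HOMER2 changed by -5.96 ± 0.53 and -5.70 ± 0.44. For a gene dim in a whole group, the bound sets the bright group's mean against the higher, per dim array, of its own signal and the lowest signal well above background.

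As groups in that fit, 14 of 14 interferon-response genes rose (14 adjusted over the list alone), with a median of 3.98 and an adjusted p of 1.59e-14 by camera, and adjusted p = 0.0335 with an estimated correlation. Of 16 T and NK cell genes, 15 rose (15 adjusted over the list alone), among them CD8A (4.82 ± 0.48), CD2 (4.33 ± 0.45) and GZMB (4.76 ± 0.67). Together they had adjusted p = 3.34e-13, and adjusted p = 0.0335 with an estimated correlation. Of 19 cytokine and chemokine genes, 13 rose (13 adjusted over the list alone), for example CCL5 (4.62 ± 0.58) and TNF (2.11 ± 0.27). Their test gave adjusted p = 6.03e-06 and 0.0335 with an estimated correlation. All 5 B-cell genes rose (5 adjusted over the list alone; adjusted p = 0.000228, and adjusted p = 0.152 with an estimated correlation). So did 10 of 13 macrophage, dendritic cell and granulocyte genes (10 adjusted over the list alone; adjusted p = 2.55e-05, and adjusted p = 0.124 with an estimated correlation). Of 9 enteroendocrine genes, 6 fell (6 adjusted over the list alone), such as the secretory granule protein CHGB (-2.44 ± 0.46) and the glucagon precursor GCG (-2.39 ± 0.51), with adjusted p = 0.000985, and adjusted p = 0.0511 with an estimated correlation. Lipid absorption genes had a median of -0.76, with 4 of 11 falling and 1 rising (5 and 1 adjusted over the list alone), adjusted p = 0.00555 and adjusted p = 0.375 with an estimated correlation. In this fit limma called 8840 features, 6086 higher and 2754 lower at day 31. Its day 1 controls were all of scan day 1 and its day 31 controls all of scan day 2, so only arrays of the other arms separate age from scan day. With scan day as a block, 5 of the 10 lists called in this fit were kept.

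With all arrays as labelled (8 against 8), 5647 features passed, 3284 higher and 2363 lower. DAPL1 (6.10 ± 0.64), the elastase inhibitor PI3, FABP6 (5.35 ± 1.34) and the membrane mucin MUC4 (at least 9.57-fold, higher on 7 of 8 arrays) led the rises, and F10 (-6.74 ± 0.49), MMP20, the apolipoprotein APOA2 and INS the falls. Among the lists that differed between both fits was lipid absorption: as labelled, 9 of 11 genes fell (9 and 1 rising adjusted over the list alone; median -2.12, adjusted p = 3.37e-08, and adjusted p = 0.245 with an estimated correlation). Its member FABP2 was at -3.98 ± 1.05 as labelled and at 0.10 without slides 6 and 7. Within scan day 1, where slide 6 holds the only day 31 arrays, IFIT1, CD8A, CCL5 and CD2 were at -0.58, -0.05, -0.06 and -0.62. With slide as the random block the count was 173, and with litter means 1604.

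In the ileum of control piglets, interferon-response, T and NK cell, B-cell and cell-cycle genes were higher at day 31, while lipid absorption, antimicrobial defence and enteroendocrine genes were lower. None of these list calls held with an estimated correlation between genes. GCSAM, a signalling protein of germinal-centre B cells, rose by 5.60 ± 0.41 (adjusted p = 6.88e-13, on 8 of 8 day 31 arrays). Higher as well were OASL (6.53 ± 0.69), CD5L (6.19), GZMK (5.92) and PHACTR3 (5.77). The zona pellucida protein ZP3 (5.25), SIX4 (at least 8.72-fold), RSAD2 (5.15 ± 0.59) and VPREB1 (5.10) rose too. AQP10, a water and glycerol channel, had the largest fall (-8.39 ± 0.77, adjusted p = 1.18e-10, on 8 of 8 arrays), before TDH, a threonine-degrading enzyme (at least 21.1-fold). ITIH4 (-6.34), HOMER2 (-5.65), BPIFB1 (-5.51), PLBD1 (-5.49), FOLH1B (-5.47), the thyroid hormone deiodinase DIO1 (-5.40), MMP20 (-4.96) and the secreted peroxidase GPX3 (-4.79) fell too. The ileal bile acid uptake transporter SLC10A2 rose by 3.71 ± 0.68 and its intracellular partner FABP6 by 2.98 ± 0.32, while the antibody transporter PIGR rose by 3.17 ± 0.75. Changes in this tissue stand against a median of all features of 0.553, which other scalings moved by up to 0.516, yet no called list changed its sign under any scaling.

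Interferon-response (14 of 14), T and NK cell (16 of 16), B-cell (5 of 5) and cell-cycle genes (8 of 8) all rose in the ileum, and adjusting over the list alone gave the same 14, 16, 5 and 8. Their adjusted p were 4.4e-05, 7.3e-05, 0.00583 and 0.0448, and adjusted p = 0.263, 0.263, 0.263 and 0.523 with an estimated correlation. Of 11 lipid absorption genes, 8 fell (8 adjusted over the list alone), including the triglyceride-forming enzyme DGAT2 (-3.72 ± 0.39) and APOC3 (-2.10 ± 0.60), with adjusted p = 4.4e-05 and adjusted p = 0.181 with an estimated correlation. Of 16 antimicrobial and epithelial defence genes, 8 fell and 1 rose (8 and 1 adjusted over the list alone; adjusted p = 0.000155, and adjusted p = 0.252 with an estimated correlation). The neutrophil proteins S100A8 (-4.42 ± 0.86), S100A9 (-3.63 ± 0.89) and S100A12 (-4.36 ± 0.84) were among those that fell, and PIGR was the member that rose. Enteroendocrine genes fell in 5 of 9 and rose in 2 (6 and 2 adjusted over the list alone), with CHGB at -3.54 ± 0.34 and the hormone CCK at -2.44 ± 0.44. The list's adjusted p was 0.00228, and adjusted p = 0.174 with an estimated correlation. The markers of other cell types moved as well: 4 of 8 fibroblast genes and 3 of 5 endothelial genes fell (4 and 3 adjusted over the list alone). They had medians of -0.84 and -0.90 and adjusted p = 0.263 and 0.174 with an estimated correlation. In total 17447 features passed (17574 without slides 6 and 7), 13302 higher and 4145 lower. The higher share of 76.2% was 50.6% after quantile normalization and 87.0% with normexp background correction.

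In the colon of control piglets, interferon-response and T-cell genes were higher at day 31, and genes of fatty acid oxidation, peptide hormones and the respiratory chain were lower. No list call of this tissue held with an estimated correlation between genes. RSAD2, which makes an antiviral nucleotide, rose by 9.12 ± 0.69 (adjusted p = 1.22e-12, on 8 of 8 day 31 arrays). It was followed by OASL (5.99 ± 0.82), IFIT3 (5.58 ± 0.52), IFI44 (5.42 ± 0.54), CD5L (5.42), ISG15 (5.19 ± 0.60), and PIK3AP1 (at least 15.0-fold). ISG12(A) (4.89), the T-cell inhibitory receptor LAG3 (4.69) and SH2D1A (4.68), an adaptor of T and NK cells, rose too. The peptide transporter SLC15A1 fell most (-5.08 ± 0.50), then the vitamin B12 carrier TCN2 (at least 13.9-fold), HSPA1L (-4.46), and YIPF5 (-4.40). The DNA topoisomerase TOP2A (-4.25 ± 0.50), BEX1 (-4.24), MGST1 (-4.12), SLC10A2 (at least 4.34-fold) and the neuropeptide GAL (-3.96) fell as well. Of 14 interferon-response genes 11 rose, and of 16 T and NK cell genes 15, among them CD3D (4.21 ± 0.44) and GZMB (4.20 ± 0.57); adjusting over the list alone gave the same 11 and 15. Their adjusted p were 0.00281 and 0.000632, and adjusted p = 0.733 and 0.484 with an estimated correlation. Fatty acid oxidation genes fell in 10 of 14 and rose in 2 (10 and 2 adjusted over the list alone), with ACADM at -2.92 ± 0.40, PLIN2, a lipid droplet coat protein, at -3.88 ± 0.36 and PDK4 at -3.39 ± 0.47. Their adjusted p was 0.00268, and adjusted p = 0.185 with an estimated correlation. Enteroendocrine genes fell in 6 of 9 and rose in 1 (6 and 1 adjusted over the list alone), with GCG at -3.63 ± 0.35, SCG2 at -3.54 ± 0.31 and somatostatin SST at -2.49 ± 0.28. Here the adjusted p was 0.00268, and adjusted p = 0.203 with an estimated correlation. Respiratory chain genes fell in 6 of 11 and rose in 1 (6 and 1 adjusted over the list alone; adjusted p = 0.0338, and adjusted p = 0.733 with an estimated correlation). Altogether 16977 features passed (16427 without slides 6 and 7), 10672 higher and 6305 lower, against a median of all features of 0.387. The higher share of 62.9% was 49.2% after quantile normalization and 86.5% with normexp background correction. Spots well above background numbered 14935 to 28109 on day 1 controls and 13053 to 21969 on day 31 controls, and a link to the changes was not tested.

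**Figure D2:**
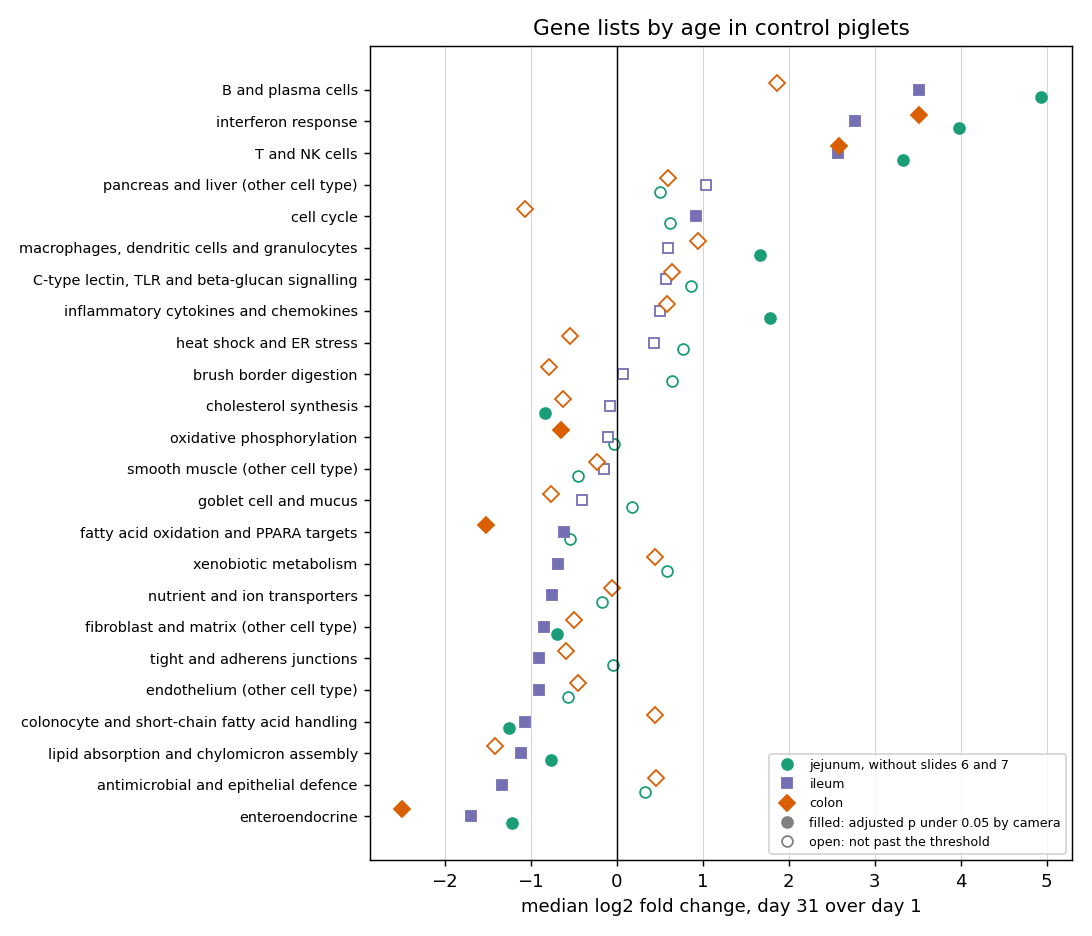
Median log2 fold change from day 1 to day 31 of each gene list (vertical axis) in control piglets, for the jejunum without slides 6 and 7 (circles), the ileum (squares) and the colon (diamonds); filled symbols passed camera's adjusted p of 0.05. T and NK cell genes have medians of 3.33, 2.58 and 2.59 in the 3 tissues and enteroendocrine genes medians of -1.21, -1.69 and -2.49, and no filled list changed its sign under another scaling. The scrapings of the 3 tissues come largely from the same control piglets, so the tissues are not independent.

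For MCFA in the jejunum at day 1, no named gene passed in either route. The named genes with the smallest p in the neonatal arm (8 against 8) were the matrix link protein HAPLN1 (-1.80 ± 0.41), PCDH7 (-1.52 ± 0.37), the ghrelin precursor GHRL (1.82 ± 0.49), DHRS7 (-1.62 ± 0.44) and IDH3B (0.81 ± 0.22), with adjusted p from 0.34. With arms from the characteristics fields, whose controls are all titled neonatal MCFA, all but PCDH7 had the opposite sign. In the maternal arm (7 against 8) they were MOS (-2.41 ± 0.57), INS (3.28 ± 0.80, adjusted p = 0.236, higher on 7 of 7 arrays), F2 (1.31), PCDH7 (-1.47) and SLC4A4 (-0.98). All had the opposite sign with arms from the characteristics fields, which set titled controls as maternal MCFA against arrays titled neonatal MCFA. Interferon-response genes had a median of 0.47 in the maternal arm (adjusted p = 0.0175, and adjusted p = 0.901 with an estimated correlation). Cell-cycle genes had a median of -0.85 (adjusted p = 0.0175, and adjusted p = 0.901 with an estimated correlation). No member of either passed (0 adjusted over the list alone). Between the routes, 8 of 8 cell-cycle genes had a positive change in the neonatal relative to the maternal arm, with a median of 1.17. Of these, 0 passed over all genes and 3 adjusted over the list alone (list adjusted p = 8.21e-06 by camera, and adjusted p = 0.448 with an estimated correlation). limma called 1, 0 and 0 features for neonatal, maternal and route, with 3201, 1656 and 1495 at an unadjusted p under 0.05. With scan day as a block the neonatal and route counts were 10103 and 10421, which rest on single arrays of scan day 3. Leaving out neonatal replicate 3 gave 12 features for neonatal, 34 for maternal and 2 for route. Without control replicate 3 or neonatal replicate 7 or 8 the neonatal count was 0. Without neonatal replicate 1 or maternal replicate 1 the maternal count was 1.

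For MCFA in the jejunum at day 31, the result depended on the 4 controls of slide 6. Without slides 6 and 7, 57 named genes passed in the neonatal arm (7 against 4), led by the antioxidant enzymes GPX2 (2.17 ± 0.48) and MGST1 (1.23 ± 0.31), hexokinase HK2 (1.87 ± 0.42), CREB3L4 (1.74), POGK (1.68) and HUS1 (1.39). The prion protein PRNP (1.36), S100A14 (1.20 ± 0.23), the sterol-synthesis enzyme NSDHL (1.16 ± 0.31) and AGPAT1 (1.12) followed. The largest falls were the antimicrobial peptide PMAP-23 (-2.02 ± 0.46), the metal-binding protein MT1A (-1.98 ± 0.50), neurolysin NLN (-1.93) and SLC11A1 (-1.79 ± 0.44), a metal transporter of phagocytes. Next came TEPP (-1.78), the inhibitory antibody receptor FCGR2B (-1.72 ± 0.37), MIOX (-1.71), MYOG (-1.69), CNPY3 (-1.69) and PAQR6 (-1.64). Of 6 cholesterol synthesis genes, 4 were higher adjusted over the list alone and 0 over all genes (median 0.95, adjusted p = 0.0133, and adjusted p = 0.67 with an estimated correlation). Respiratory chain genes had a median of 0.42 in that arm with 11 of 11 positive (0 passing, 0 adjusted over the list alone; adjusted p = 0.000415, and adjusted p = 0.67 with an estimated correlation). The 4 controls left are all on 1 slide. In that fit 1303 features passed for neonatal, 212 higher and 1091 lower, and 0 for maternal and for route, with 2753 and 1861 at an unadjusted p under 0.05.

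With all arrays as labelled, limma called no feature in the day 31 jejunum for either route or between them (3528, 2927 and 1109 at an unadjusted p under 0.05). The smallest p in the neonatal arm (7 against 8) belonged to AGPAT4 (1.5 ± 0.31), HNF4A (1.14 ± 0.26) and the complement genes C1QA (1.80 ± 0.38), C1QB (1.83 ± 0.41) and C1QC (1.66 ± 0.37), all with adjusted p = 0.204. In the maternal arm (6 against 8) it belonged to the eotaxin receptor CCR3 (2.76), the defensin DEFB1 (-3.76), MEG3 (-1.71) and TMEM57 (0.56). T and NK cell genes had a median of 1.99 in the neonatal arm (9 of 15 higher adjusted over the list alone; adjusted p = 4.85e-09, and adjusted p = 0.395 with an estimated correlation). Their median was 1.96 in the maternal arm (1 adjusted over the list alone; adjusted p = 7.54e-10, and adjusted p = 0.284 with an estimated correlation). Without slides 6 and 7 the medians of T and NK cell genes were 0.17 and -0.11 in these arms, and camera called neither. Smooth muscle genes, a marker list of another cell type, had medians of -0.39 and -0.68 in the same arms (1 and 0 lower adjusted over the list alone; adjusted p = 0.0307 and 0.00168, and adjusted p = 0.439 and 0.284 with an estimated correlation). Leaving out control replicate 6 or 8, or neonatal replicate 1 or 4, gave 9, 1, 5 and 2 features for neonatal. Leaving out control replicate 1 or 6 or neonatal replicate 5 gave 2, 1 and 1 for maternal.

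For β-glucans in the ileum at day 1, the neonatal arm (6 against 8) had lower signals of 29 named genes and higher signals of 2. SLC11A1 fell by 1.53 ± 0.30 on the log2 scale (adjusted p = 0.00372) and FCGR2B by 1.36 ± 0.23 (adjusted p = 0.00145), each lower on 6 of 6 arrays than the control mean. Next were the NK-cell receptor KIR2DL1 (-1.31 ± 0.27), the muscle transcription factor MYOG (-1.29 ± 0.28), NLN (-1.28 ± 0.25), and the cyclic AMP phosphodiesterase PDE4A (-1.25). CNPY3 (-1.07 ± 0.20), a chaperone of Toll-like receptors, the adrenergic receptor ADRB1 (-1.03), the blood-cell transcription factor GATA2 (-0.98) and TP23 (-0.97) fell as well. ECI2, an enzyme of unsaturated fatty acid oxidation, rose by 0.86 ± 0.22 and SELENOT by 0.45 ± 0.13. No gene list was called for either route against control. Of 1014 features that passed, 36 were higher and 978 lower, and 31 had a gene name; with same-route controls the count was 21, and without slide 7 it was 1182. Slide as the random block gave 1129, but at the slide correlation that the lower features had in other tissues and ages (median 0.529) 12 of the 978 passed. With arms from the characteristics fields, which contradict the titles, the count was 0 and all of these genes had the opposite sign, SLC11A1 for example 1.14 and FCGR2B 1.00. Those fields give every array titled β-glucan here as a control, and their neonatal β-glucan arrays are titled controls. The opposite sign thus follows from the exchange of arms. Other probes of SLC11A1, FCGR2B, NLN, PDE4A and TP23 correlated at only 0.263, 0.348, 0.258, 0.176 and 0.462 with the probe used.

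In the maternal arm of the same tissue and day (7 against 8) no named gene passed. The smallest p belonged to CAMK1G (-0.94 ± 0.19, adjusted p = 0.0662, lower on 7 of 7 arrays), IFN-ALPHA-10 (-0.97), AQP2 (-0.58), KIR2DL1 (-1.11) and KCNA5 (-0.67). Without the array of slide 7, KIR2DL1 (-1.29 ± 0.20), CAMK1G (-1.01 ± 0.18), the cytokine TNFSF12 (-0.98 ± 0.18), the antigen peptide transporter TAP2 (-0.73 ± 0.14) and AQP2 (-0.63 ± 0.13) fell. Between the routes SMN1, which serves spliceosome assembly, was lower in the neonatal arm by 1.36 on the log2 scale (-1.36 ± 0.24, adjusted p = 0.0358). Lipid absorption genes had a median of 0.57 between the routes (1 of 11 adjusted over the list alone; adjusted p = 0.0263, and adjusted p = 0.784 with an estimated correlation). T and NK cell genes had one of -0.60 (0 adjusted over the list alone; adjusted p = 0.0263, and adjusted p = 0.976 with an estimated correlation). limma called 1 feature for maternal (50 without slide 7) and 41 between the routes (73 without slide 7). The maternal count was 2 without control replicate 2, neonatal replicate 4 or 6 or maternal replicate 1. It was 62, 201, 6 and 22 without neonatal replicate 1, neonatal replicate 5, maternal replicate 4 and maternal replicate 7. The last is the array of slide 7. The 22 kept the litter correlation of all arrays (0.329), while the 50 had it estimated anew (0.286). The route count was 5, 6, 11, 5, 25 and 18 without control replicates 1, 2, 3, 4, 7 and 8. It was 26, 7, 1, 284 and 6 without neonatal replicates 1, 2, 3, 5 and 6, and 13, 5, 5, 4 and 4 without maternal replicates 1 to 5.

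For β-glucans in the ileum at day 31, the maternal arm (7 against 8) had a higher signal of the lymphoid chemokine CCL19 (1.47 ± 0.41, adjusted p = 0.0431, on 6 of 7 arrays) and the calcification inhibitor MGP (1.02 ± 0.25). The stress cytokine GDF15 (0.88 ± 0.19, adjusted p = 0.0236), cyclin CCND3 (0.88 ± 0.23), CSNK2B (0.61) and PAFAH1B1 (0.45) also rose. Larger falls were seen in SPAM1, a hyaluronidase best known from sperm (-3.12 ± 0.77), the urothelial protein UPK1A (-2.85 ± 0.65), the steroid hydroxylase CYP21A2 (-2.70 ± 0.62), FAM216B (-2.47), ADRA2B (-2.33) and IFN-DELTA-1 (-2.32). GPX6 (-2.26 ± 0.44), TRPV4 (-1.90), the lipid antigen-presenting CD1E (at least 1.91-fold), ACACB (-1.85 ± 0.40) and complement factor CFB (-1.04 ± 0.29) fell as well. Macrophage, dendritic cell and granulocyte genes had a median of 0.41 (12 of 13 positive, 0 passing and 0 adjusted over the list alone; adjusted p = 0.000234, and adjusted p = 0.403 with an estimated correlation). Respiratory chain genes had one of 0.22 (1 of 11 adjusted over the list alone; adjusted p = 0.000416, and adjusted p = 0.403 with an estimated correlation). Of the 9 lists called in the maternal arm, 3 others had medians from 0.19 to 0.22 that turned to between -0.04 and -0.02 with normexp background correction. In the neonatal arm (6 against 8) no feature passed (limma, 1271 at an unadjusted p under 0.05). CCL19 was at 1.62 ± 0.39, LEF1 at 1.17, SLA-DOB at 0.87, CCR7 at 1.20 and RSC1A1 at 0.55, all with adjusted p = 0.936. Interferon-response genes had a median of 0.42 in that arm (14 of 14 positive, 0 adjusted over the list alone; adjusted p = 3.72e-06, and adjusted p = 0.681 with an estimated correlation).

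Of the 1389 features that passed in the maternal arm, 54 were higher and 1335 lower, 58 of them with a gene name, against a median of all features of -0.20. The lower features lay at a median percentile of 29.3 of mean signal and the higher ones at 66.6, so many falls are of dim probes. The count was 12 after quantile normalization and 10316 with normexp background correction, and 0 with same-route controls. Leaving single arrays out, it was 47, 154 and 3735 without control replicates 2, 3 and 6, 773 and 866 without neonatal replicates 1 and 2, and 448, 594, 314, 371, 2604 and 286 without maternal replicates 1 to 6. Between the routes no feature passed (2245 at an unadjusted p under 0.05; 1 without control replicate 5 and 2 without neonatal replicate 5). Respiratory chain genes had a median of -0.31 in the neonatal arm relative to the maternal arm (0 of 11 positive, 0 adjusted over the list alone; adjusted p = 2.54e-08, and adjusted p = 0.1 with an estimated correlation).

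For GOS in the colon at day 1, the neonatal arm (8 against 6) showed no feature past the threshold (limma, 1149 at an unadjusted p under 0.05). The smallest p belonged to LPCAT4 (-0.77), CRABP1 (-1.70), the bacterial sensor NOD2 (-1.60), CIDEA (-1.20) and SLC9A3R2 (-0.89), with adjusted p from 0.703. Smooth muscle genes had a median of -0.93 (0 of 7 positive, 0 adjusted over the list alone; adjusted p = 0.00341, and adjusted p = 0.676 with an estimated correlation). Antimicrobial genes had one of -0.63 (0 adjusted over the list alone; adjusted p = 0.0284, and adjusted p = 0.676 with an estimated correlation). Leaving out control replicate 1 or 3 gave 3 and 1 features.

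The 5 arrays labelled day 1 colon GOS maternal, all on slide 7, differed from the 6 controls in small-intestinal, lymphocyte and colonocyte genes. The interferon-induced gene RSAD2 was higher by 9.07 ± 1.08, FABP2 by 9.05 ± 1.61, the antimicrobial lectin REG3G by 8.94 ± 1.72, CCL25 by 8.12 ± 0.47 (adjusted p = 8.49e-10, on 5 of 5 arrays), and C4BPA by 8.07. OASL was higher by 7.65, the chylomicron assembly protein MTTP by 7.03 ± 0.95 and GZMA by 7.02. The urea-cycle enzyme OTC and the glucose transporter SLC2A2 were higher at least 224-fold and 43.5-fold. Lower were the estrogen sulfotransferase SULT1E1 (-8.63 ± 0.53), ANXA8 (at least 82.7-fold), and the peroxide-forming DUOX2 (-7.43 ± 1.14) and its partner DUOXA2 (-7.16 ± 1.04). UCP3 (-7.26), CLDN8 (at least 26.3-fold), the carbonic anhydrase CA4 (-6.12 ± 0.55), the sodium channel subunit SCNN1G (at least 10.5-fold) and UPK3A (-5.80) were lower as well. T and NK cell genes rose in 15 of 15 (15 adjusted over the list alone; median 4.73, adjusted p = 1.9e-17, and adjusted p = 0.00611 with an estimated correlation). Colonocyte genes fell in 7 of 9 (7 adjusted over the list alone; median -2.90, adjusted p = 5.63e-05, and adjusted p = 0.138 with an estimated correlation). Nutrient transporter genes rose in 9 of 11 and fell in 2 (9 and 2 adjusted over the list alone; adjusted p = 0.000102, and adjusted p = 0.114 with an estimated correlation). In all, 6974 features passed against control, 3373 higher and 3601 lower, and 5697 between the routes. There SULT1E1 (9.15) was higher and FABP2 (-11.08) and REG3G (-9.70) lower in the neonatal arm. Without slides 6 and 7 no GOS maternal array is left at day 1, so both comparisons have no value.

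For GOS in the colon at day 31, the maternal arm (4 against 8) had lower signals of the interferon-induced genes IFIT3, RSAD2 and IFI44 and higher signals of LYZ and 2 complement genes. IFIT3 fell by 3.21 ± 0.54 on the log2 scale (adjusted p = 0.0134), RSAD2 by 2.95 ± 0.61 (adjusted p = 0.0244) and IFI44 by 2.70 ± 0.51 (adjusted p = 0.0231), each lower on 4 of 4 arrays. FAM216B fell at least 2.67-fold, C1QTNF7 at least 2.3-fold and the copper transporter SLC31A2 at least 3.67-fold. The paracellular channel protein CLDN15 (-2.64 ± 0.69), TRPC1 (-2.62), the shared cytokine receptor chain IL2RG (-2.61 ± 0.58), osteopontin SPP1 (-2.46) and the chloride channel CFTR (-2.04 ± 0.49) were lower too. LYZ, the antibacterial lysozyme, rose by 4.28 ± 1.23 (adjusted p = 0.0435, on 4 of 4 arrays), with signals of single controls between -3.29 and 2.56. TCN2 (at least 2.93-fold), PDE6C (1.96), the fatty acid oxidation enzyme HADH (1.89 ± 0.40), the complement genes C1QC (1.81 ± 0.44) and C1QB (1.62 ± 0.39) and HSD11B2, which inactivates cortisol (1.76), also rose. The lysosomal CLN3 (1.85), NAGS (1.70) and KLF16 (1.63) rose too, but with normexp background correction they were at -0.18, -0.21 and -0.28. The interferon-response list was not called: 3 of its 14 genes fell (4 adjusted over the list alone; median -0.85, adjusted p = 0.102, and adjusted p = 0.688 with an estimated correlation). Respiratory chain genes had a median of 0.71 (11 of 11 positive, 0 passing and 0 adjusted over the list alone; adjusted p = 0.000926, and adjusted p = 0.659 with an estimated correlation). Colonocyte genes rose in 2 of 8, among them GUCA2B (2 adjusted over the list alone; adjusted p = 0.00611, and adjusted p = 0.216 with an estimated correlation). Fatty acid oxidation genes rose in 1 of 13 (3 adjusted over the list alone; median 0.57, but -0.01 with normexp background correction; adjusted p = 0.00611, and adjusted p = 0.294 with an estimated correlation).

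Of the 1373 features that passed in that arm, 170 were higher and 1203 lower, 152 of them with a gene name, against a median of all features of -0.24. The count was 0 with slide as the random block, 4 with normexp background correction and 264 after quantile normalization. It was 0 with arms from the characteristics fields, 5 with same-route controls and 10562 with array weights. Leaving single arrays out, it was 47, 131, 552 and 898 without control replicates 2, 3, 5 and 8. It was 2817, 566, 732 and 849 without neonatal replicates 2, 3, 4 and 8, and 577, 2970, 0 and 0 without maternal replicates 1 to 4. In the neonatal arm (8 against 8) no feature passed (limma, 244 at an unadjusted p under 0.05). The smallest p belonged to the neuropeptide NPY (1.28), YIPF3 (0.80), MTTP (-2.59), FABP2 (-3.05) and RBP2 (-1.80). Macrophage, dendritic cell and granulocyte genes had a median of 0.36 there (13 of 13 positive, 0 adjusted over the list alone; adjusted p = 3.98e-05, and adjusted p = 0.205 with an estimated correlation). Smooth muscle genes were at 0.44 (7 of 7 positive, 0 adjusted over the list alone; adjusted p = 0.000194, and adjusted p = 0.205 with an estimated correlation). Of the 8 lists called there, fatty acid oxidation alone turned its sign with normexp background correction (0.22 to -0.03).

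Between the GOS routes at day 31 (8 against 4), IFIT3 (3.53 ± 0.54, adjusted p = 0.0132), RSAD2 (3.00 ± 0.61), IFI44 (2.54 ± 0.51), the antiviral kinase EIF2AK2 (2.09 ± 0.40) and LHX2 (at least 1.78-fold) were higher in the neonatal arm. IFIT3, RSAD2 and IFI44 were so on 8 of 8 arrays each. Interferon-response genes were higher in 3 of 14 (8 adjusted over the list alone; median 1.5, adjusted p = 0.00432, and adjusted p = 0.643 with an estimated correlation). Of 100 features that passed, 99 were higher in the neonatal arm, and the count was 0 after quantile normalization and with slide as the random block. On leaving out 1 array it was 27, 50, 30, 58, 31 and 185 without control replicates 1, 3, 4, 5, 7 and 8. It was 33, 3285, 22, 288, 12, 47, 56 and 8 without neonatal replicates 1 to 8, and 22, 2259, 0 and 0 without maternal replicates 1 to 4.

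**Figure D3:**
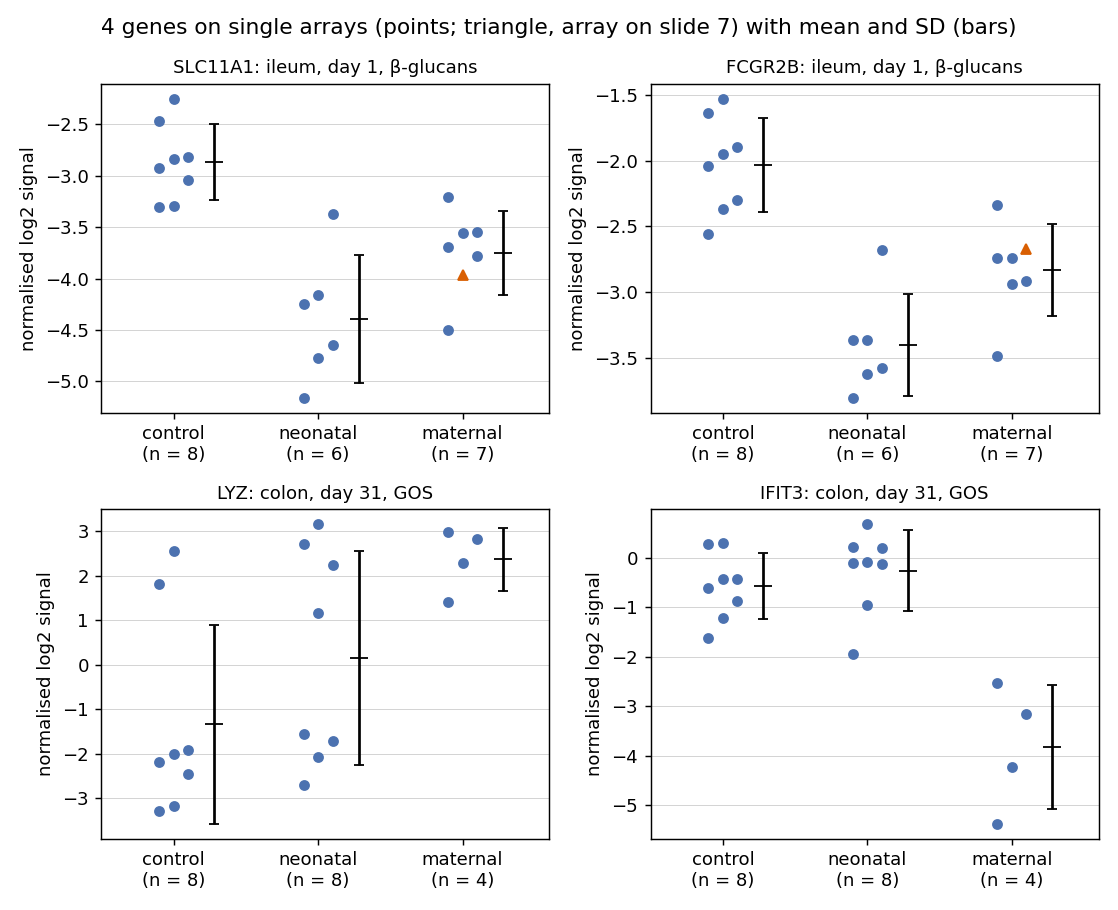
Normalised log2 signal of SLC11A1 and FCGR2B in the day 1 ileum and of LYZ and IFIT3 in the day 31 colon, by arm; points are single arrays, bars are means with SD, and the triangle is the array of slide 7. The 4 GOS maternal arrays have IFIT3 signals from -5.37 to -2.53, below every control, and LYZ signals from 1.41 to 2.98, while controls of LYZ fall into separate ranges.

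Whether an additive acted differently at both ages was tested as the difference of its effects. In the colon the arrays labelled GOS maternal gave 10144 features, 3379 higher and 6765 lower, led by SULT1E1 (10.57), ANXA8 (8.48), DUOX2 (7.38) and UCP3 (7.32), and by FABP2 (-12.78), RSAD2 (-11.70), MTTP (-10.28), REG3G (-10.04) and CCL25 (-9.93). The 5 arrays of slide 7 enter these values, and without them the test has no value. Of the 14 lists called there, enteroendocrine genes alone turned their sign with normexp background correction (1.52 to -0.04). Colonocyte genes were higher in 7 of 9 (8 adjusted over the list alone; median 3.11, adjusted p = 1.95e-07, and adjusted p = 0.0193 with an estimated correlation). For neonatal MCFA in the jejunum, 245 features passed as labelled, with the antibody transporter PIGR (6.17), CCL26 (5.90), LYZ (5.27 ± 1.12), C4BPA (4.70) and MMP3 (3.83) more positive at day 31. More negative were MUC4 (-4.26), LY6G6D (-3.85), UPK1B (-3.65), C3H2orf40 (-3.61) and RBP5 (-3.32), and without slides 6 and 7 the count was 11. For maternal MCFA it was 58 as labelled, with LYZ (5.11), CCR3 (3.37), AGPAT2 (1.56) and RTN1 (-2.84), and 2 without those slides. For β-glucans 57 (neonatal) and 7 (maternal) features passed, none with a gene name (54 and 4 without slide 7), and for neonatal GOS 0 (limma, 1637 at an unadjusted p under 0.05). Smooth muscle genes had a median of 1.31 in that last test (6 of 7 adjusted over the list alone; adjusted p = 3.21e-08, and adjusted p = 0.221 with an estimated correlation). Leaving out 1 array moved these counts by more than 1.5 times for 21, 18, 40 and 28 arrays and for 1 array of neonatal GOS (1, without day 1 neonatal replicate 2). The extremes were 44 and 727 without day 31 control replicates 4 and 6 for neonatal MCFA, and 15 and 180 without day 31 maternal replicate 5 and day 31 control replicate 5 for maternal MCFA. For β-glucans they were 0 and 415 without day 1 control replicate 1 and day 31 control replicate 2 for neonatal, and 1 and 26 without day 1 control replicate 1 and day 1 neonatal replicate 1 for maternal. Where several arrays gave the same extreme, only the first is named. Leaving out any of 40 of the 42 ileum arrays moved the neonatal β-glucan count of 57.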

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

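The arrays of slides 6 and 7 had profiles of another tissue or age than their labels; the 3 tests of this pattern given here were chosen after the result was seen, and CA4 in the third after its values were seen. On the slide positions filled on both slides, 8 of 8 arrays had the sex signature of the label at the same position of the other slide, against 4 for their own label, which is consistent with an exchange of the contents of both slides. Only the 2 positions with different labelled sexes inform this test, with all 4 arrays there matching the other slide's label. The tissue and age profile fitted the label of the other slide on 7 of 8 arrays and the own label on 0, while day 1 colon GOS maternal replicate 4 fitted day 31 ileum. An effect of the additive does not account for it, since 4 control arrays were out of place too. A mixture with another tissue's RNA is not in line with a gap of 4.08 on the log2 scale in CA4 between the 5 arrays labelled day 1 colon GOS maternal and the lowest other day 1 colon array, where a mixture leaving 0.1 of the colon RNA would give 3.32. The labels were kept, and the exchange itself cannot be checked from the files.

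In the day 1 ileum, falls under neonatal β-glucan far outnumbered rises. The 4 tests of slide and that of dim probes were chosen after the result was seen, and those of a single array and scan day before. The scan-day block was itself an alternative added after the data were seen. Neither 1 array nor scan day explains the count, which was 1325 without the array with the most detected spots and 1289 with scan day as a block. A difference between slides could explain part of it: in other tissues and ages slide accounted for 71.7% of the spread within groups in the mean level of the 978 lower features (permutation p = 1e-05 from 100000 shuffles, the smallest possible; median of shuffles 20.5%). The shuffles part littermates, and most littermates lie on 1 slide. In the 24 maternal arrays among these, with 1 piglet per litter, slide accounted for 77.2% (permutation p = 0.0017; median of shuffles 17.8%). The planned fit with slide as the random block kept the count, at 1129, which goes against slide. It used the slide correlation of all features of 0.094, while the lower features had 0.325 to 0.842 in the 5 other tissue and age fits. At their median of 0.529, 12 of the 978 still passed: the median change went from -1.1 to -1.01 and the median SE from 0.23 to 0.32, so the call ended by the wider SE. With slide as an additive term over all tissues and ages, the difference in the mean level of the lower features went from -1.17 ± 0.25 to -0.61 ± 0.33. These features were chosen for their fall in this comparison, so both differences can be too large. Both fits left out litter and sex, so their SE can be too small. The difference with slide in the fit was -1.56 without the arrays of this arm on slide 20 and -0.41 without that on slide 22. The latter array lay at -4.17, against -2.33 and -3.43 on the day 1 jejunum and colon arrays of slide 22. The jejunum and colon arrays had 40.37% and 43.04% of spots well above background, against 67.52% on the β-glucan array. Slide and signal strength cannot be told apart there. Slide therefore stays open as an explanation. Dim probes do not explain the falls, which lie at a median percentile of 66.8 of signal. Of 977 of these features, 573 also fell under neonatal MCFA in the day 31 jejunum without slides 6 and 7, where 41.4 would be shared by independent lists. No array is shared, but the 4 jejunum controls left come from 2 litters that also gave 4 of the 8 day 1 ileum controls, so a difference of these litters is not excluded. These controls all lie on slide 8, at a mean level of -1.92, against -3.34 to -3.26 on the slides of the MCFA arm. A slide difference is thus not excluded for this overlap either, as features that vary together with slide are not independent. The day 1 ileum falls shared 80 with the falls under maternal β-glucan in the day 31 ileum (42.1 for independent lists) and 26 with those under maternal GOS in the day 31 colon (51.1). An action of both additives on the same genes is not excluded; slide 21 alone holds both arms, with 1 array of each.

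In the day 31 colon, many features differed under maternal GOS; the test of a later age shift was chosen after the result was seen, and those of a single array and slide before. The count was 0 on leaving out replicate 3 or 4 of that arm and 0 with slide as the random block, yet the folds stayed. The median of the 1203 lower features went from -1.8 (median SE 0.47) to -1.7 (0.52), -1.54 (0.49) and -1.88 (0.55) in these fits, and IFIT3 from -3.21 ± 0.54 to -3.08 ± 0.60, -2.70 ± 0.53 and -3.17 ± 0.68. The features were chosen in the full fit of the same arrays, which favours kept folds. No 2 arms here share a slide, so a random block cannot take a slide difference out of the folds. Fewer arrays or a wider SE could end the calls as well as a single array or slide, so these tests do not decide. A later age shift in these piglets may also be at work. Of the 170 higher features 91.8% fall from day 1 to day 31 in the neonatal GOS arm, against 39.7% of all 20710 tested. Of the 1203 lower ones 98.7% rise there, against 60.3% of all tested. Signal strength differed too: 20289 to 23174 spots lay well above background on the 4 maternal arrays and 13053 to 21969 on the controls. In the neonatal GOS arm it was 18853 to 29851 at day 1 and 16946 to 25736 at day 31. Whether signal strength made the pattern was not tested. With 4 arrays these explanations cannot be told apart.

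The splits of the arrays into groups of the same sizes were chosen before the results were seen and show whether chance can be excluded, as the number of 100 groupings, the real one included, with at least the real count. They were run on features with a value on every array, so the real counts differ from those of the main fits (for example 12 against 7 for the age-dependence of maternal β-glucan). They used all arrays as labelled, those of slides 6 and 7 included, with no allowance for the number of comparisons. They move single arrays and part littermates and arrays of the same slide. The splits thus speak to chance in single arrays and not to a difference between litters or between slides. In this sense chance can be excluded for age in control jejunum (1, real count 5607, highest other 2182), ileum (1, real 16841, other 11118) and colon (1, real 16867, other 13463). It can be excluded for neonatal β-glucan in day 1 ileum (1, real 1005, other 571), its route contrast (3, real 46, other 199) and maternal β-glucan in day 31 ileum (2, real 1397, other 4421), where splits calling several times the real count point to a structure of the samples. The same goes for the arrays labelled maternal GOS in day 1 colon (1, real 6937, other 2485) and their route contrast (1, real 5661, other 50). These arrays resemble another tissue and age, so the counts cannot be read as an effect of GOS in the colon. In day 31 colon chance can be excluded in the same sense for maternal GOS (1, real 1373, other 5) and the routes (1, real 100, other 1). For neonatal MCFA in day 1 jejunum 2 groupings reached its 1 feature, with a highest other of 1. Of the age-dependences, chance can be excluded for neonatal MCFA (1, real 241, other 1), neonatal β-glucan (1, real 63, other 0), maternal β-glucan (4, real 12, other 1610; 4 also reach the 7 of the main fit, near the limit of 5) and maternal GOS (1, real 10101, other 2768). It cannot be excluded for the age-dependence of maternal MCFA (5, real 58, other 1161) and for maternal β-glucan in day 1 ileum (6, real 1, other 11). Without slides 6 and 7 the age-dependence of neonatal MCFA had 11 features rather than 245, so its split speaks to the labelled groups alone. All 100 groupings reached the real count of 0 for maternal MCFA and the routes in day 1 jejunum (highest other 1 and 6), for neonatal MCFA, maternal MCFA and the routes in day 31 jejunum (1273, 3913 and 0), and for neonatal β-glucan and the routes in day 31 ileum (22 and 3). The same 100 held for neonatal GOS in day 1 colon (3), day 31 colon (251) and in its age-dependence (4); the 1273 and 3913 also point to a structure of the samples.

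Of 72 groups and measures, 10 held an array beyond Dixon's critical value, where chance alone gives about 1 in 20. The percent of spots well above background was 83.17 on day 31 ileum β-glucan maternal replicate 5, 73.76 on day 1 jejunum control replicate 1, 40.37 on day 1 jejunum MCFA neonatal replicate 3 and 84.54 on day 31 jejunum MCFA neonatal replicate 4. RSAD2 was at -2.53 on day 1 colon GOS maternal replicate 1 and SULT1E1 at 1.04 on day 1 colon control replicate 4. F10 and MMP20 were at -3.82 and -2.35 on day 31 jejunum control replicate 1, an array of slide 6. TDH was at -10.61 on day 1 ileum control replicate 2 and OASL at -3.56 on day 31 colon control replicate 2. Effects that differed between ages numbered 245 and 58 features for neonatal and maternal MCFA, 57 and 7 for neonatal and maternal β-glucan, and 10144 for maternal GOS, the last with the arrays of slide 7. Without slides 6 and 7 they numbered 11 and 2 for MCFA and 54 and 4 for β-glucan.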

How the results depend on the processing

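In most alternatives most counts of 0 kept their call, and age in ileum and colon controls stayed within 1.5 times. Several other counts, such as maternal β-glucan and maternal GOS at day 31 and most age-dependences, moved in many alternatives. The counts that moved follow by tissue. The cause of a move was not tested unless stated. Signal over background limits what a dim probe can show, so fold changes against a dim group are lower bounds, and normexp acts most on those probes. The alternatives without slides 6 and 7, without the 15 arrays in doubt, with scan day as a block, within a scan day and with a percentile over all probes were added after the data were seen. The fit with no replicate block, which leaves litter out of the model, moved 8 counts; for example it called 1565 features instead of 1014 for neonatal β-glucan in day 1 ileum. Neonatal β-glucan in day 31 ileum and neonatal GOS in day 31 colon stayed at 0 throughout, and age in ileum controls (17447) stayed within 1.5 times, from 13769 to 21018. Doubted arrays are those with a tissue, age or sex signature against their label.

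Scaling moved the median log2 fold change of all features by more than 0.1 in 14 comparisons with quantile normalization (from -0.516 to 0.384), 19 with normexp (from -0.517 to 0.717), 14 with normexp and quantile (from -0.511 to 0.35) and 9 with the all-probe percentile (from -0.308 to 0.251). The share of higher features moved by over 10 points with quantile normalization for age in ileum controls (76.2% to 50.6%), age in colon controls (62.9% to 49.2%), maternal β-glucan in day 31 ileum (3.89% to 25%) and maternal GOS in day 31 colon (12.4% to 35.2%). The same held for the age-dependence of neonatal MCFA (66.9% to 38.9%) and of maternal GOS (33.3% to 48.1%), and for neonatal MCFA in day 1 jejunum, which has 1 feature (0% to 50%). With normexp it moved for maternal GOS in day 1 colon (48.4% to 32.6%) and day 31 colon (to 0%), the age-dependence of neonatal MCFA (to 22.2%), and age in ileum (to 87%) and colon (to 86.5%). With normexp and quantile the shares were 50.3% for maternal GOS in day 31 colon, 45.6% and 48.9% for those age-dependences, and 52.4% and 50% for age in ileum and colon. With the all-probe percentile they were 18% for maternal β-glucan in day 31 ileum, 34.2% for maternal GOS in day 31 colon, 54.3% and 44.5% for the age-dependences and 59.8% for age in ileum.

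Against 1 for neonatal MCFA in day 1 jejunum, the count was 0 with arms from the characteristics, litter means, normexp, normexp with quantile, same-route controls and slide block, 2 with quantile normalization, 8 with no replicate block, 30 with array weights and 10103 with scan-day block. Against 0 for maternal MCFA in day 1 jejunum, the count was 15 with no sex term and scan-day block, 16 with 2 arms alone, 17 with scan day 1 alone, 22 with litter means and 43 with array weights. Against 0 for the MCFA routes in day 1 jejunum, the count was 1 with array weights, 7 with litter means and 10421 with scan-day block. Against 0 for neonatal MCFA in day 31 jejunum, the count was 1 with no sex term, normexp, normexp with quantile and the strict filter, 2 with same-route controls, 3 with quantile normalization, 5 with array weights and 8 with no replicate block. It reached 1303 with slides 6 and 7 left out, 1335 with doubted arrays left out and 1383 with scan-day block. Against 0 for maternal MCFA in day 31 jejunum, the count was 1 with scan day 2 alone and 3 with arms from the characteristics. Against 0 for the MCFA routes in day 31 jejunum, the count was 1 with scan day 2 alone. Against 5647 for age in jejunum controls, the count was 173 with slide block, 1604 with litter means, 8717 with array weights, 8840 with slides 6 and 7 left out and 9149 with doubted arrays left out. Against 245 for the age-dependence of neonatal MCFA in the jejunum, the count was 0 with litter means and slide block, 11 with slides 6 and 7 left out, 42 with no filter, 76 with no replicate block and 81 with normexp. It was 372 with the strict filter, 385 with single probes, 460 with quantile normalization, 504 with normexp with quantile and 586 with array weights. It reached 3839 with scan-day block. Against 58 for the age-dependence of maternal MCFA in the jejunum, the count was 0 with litter means, normexp and slide block, 2 with scan-day block and slides 6 and 7 left out, 20 with no filter, 22 with no replicate block and 29 with normexp with quantile. It reached 166 with doubted arrays left out and 175 with array weights. On leaving out 1 array the count ran from 0 to 12 for neonatal MCFA in day 1 jejunum, 0 to 34 for maternal MCFA in day 1 jejunum and 0 to 2 for the MCFA routes in day 1 jejunum. Likewise it ran from 0 to 9 for neonatal MCFA in day 31 jejunum, 0 to 2 for maternal MCFA in day 31 jejunum and 44 to 727 for the age-dependence of neonatal MCFA in the jejunum. The last such ranges were 15 to 180 for the age-dependence of maternal MCFA in the jejunum.

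Against 1014 for neonatal β-glucan in day 1 ileum, the count was 0 with arms from the characteristics, 21 with same-route controls, 617 with litter means, 1565 with no replicate block and 2295 with array weights. Against 1 for maternal β-glucan in day 1 ileum, the count was 0 with litter means, same-route controls and scan-day block, 3 with normexp and quantile normalization, 4 with the all-probe percentile, 5 with normexp with quantile and 14 with the strict filter. It reached 50 with slides 6 and 7 left out, 95 with array weights, 213 with no replicate block and 369 with 2 arms alone. Against 41 for the β-glucan routes in day 1 ileum, the count was 5 with no filter, 6 with slide block, 24 with no sex term, 27 with litter means and 66 with normexp. It reached 73 with slides 6 and 7 left out, 90 with normexp with quantile, 140 with scan-day block, 151 with no replicate block and 603 with array weights. Against 1389 for maternal β-glucan in day 31 ileum, the count was 0 with same-route controls, 1 with normexp with quantile, 12 with quantile normalization, 199 with 2 arms alone and 286 with doubted arrays left out. It reached 328 with no sex term, 539 with litter means, 690 with the all-probe percentile, 4350 with no filter and 10316 with normexp. Against 0 for the β-glucan routes in day 31 ileum, the count was 7 with litter means and 366 with array weights. Against 57 for the age-dependence of neonatal β-glucan in the ileum, the count was 0 with litter means, no filter, normexp and slide block, 5 with scan day 2 alone, 131 with quantile normalization, 138 with the strict filter and 146 with the all-probe percentile. It reached 153 with doubted arrays left out, 184 with normexp with quantile, 245 with scan-day block and 1452 with array weights. Against 7 for the age-dependence of maternal β-glucan in the ileum, the count was 0 with normexp, normexp with quantile, quantile normalization and the strict filter, 1 with no filter, no sex term, scan-day block and slide block, 2 with the all-probe percentile, 3 with litter means and 4 with doubted arrays left out and slides 6 and 7 left out. It reached 85 with array weights. On leaving out 1 array the count ran from 1 to 201 for maternal β-glucan in day 1 ileum, 1 to 284 for the β-glucan routes in day 1 ileum and 47 to 3735 for maternal β-glucan in day 31 ileum. Likewise it ran from 0 to 2 for the β-glucan routes in day 31 ileum, 0 to 415 for the age-dependence of neonatal β-glucan in the ileum and 1 to 26 for the age-dependence of maternal β-glucan in the ileum.

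Against 0 for neonatal GOS in day 1 colon, the count was 895 with scan-day block. Against 6974 for maternal GOS in day 1 colon, the count was 2286 with normexp. Against 5697 for the GOS routes in day 1 colon, the count was 1801 with normexp and 11681 with array weights. Against 1373 for maternal GOS in day 31 colon, the count was 0 with arms from the characteristics and slide block, 4 with normexp, 5 with same-route controls, 31 with no filter and 103 with scan day 2 alone. It reached 264 with quantile normalization, 467 with normexp with quantile, 667 with 2 arms alone and 10562 with array weights. Against 100 for the GOS routes in day 31 colon, the count was 0 with quantile normalization and slide block, 3 with normexp and normexp with quantile, 10 with no filter, 14 with the all-probe percentile and 26 with the strict filter. It reached 34 with scan day 2 alone, 318 with no replicate block, 615 with scan-day block and 10099 with array weights. Against 16977 for age in colon controls, the count was 28650 with no filter. Against 0 for the age-dependence of neonatal GOS in the colon, the count was 1 with quantile normalization. Against 10144 for the age-dependence of maternal GOS in the colon, the count was 4150 with normexp and 4546 with slide block. On leaving out 1 array the count ran from 0 to 3 for neonatal GOS in day 1 colon, 0 to 2970 for maternal GOS in day 31 colon and 0 to 3285 for the GOS routes in day 31 colon. Likewise it ran from 0 to 1 for the age-dependence of neonatal GOS in the colon.

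Gene list calls numbered 176, against 3 with an estimated correlation, 91 with fry and 134 with scan day as a block, each counted over all lists tested; of the 176, the 3, 69 and 97 were also called by these. Of the changes of named genes followed across the alternatives, few turned their sign outside the fits with arms from the characteristics fields. With those arms 21 turned their sign, 21 kept it but no longer passed and 5 kept their call. In day 1 ileum, and for maternal MCFA in day 1 jejunum, those arms take titled controls as additive arrays and titled additive arrays as controls. The turned signs there are therefore no independent check. For neonatal MCFA in day 1 jejunum neither of those arms holds a titled control. They set arrays titled neonatal or maternal MCFA against arrays titled neonatal MCFA, so they do not test the titled comparison either. With arms from the characteristics in day 1 jejunum, HAPLN1 was at 0.28, GHRL at -0.60, DHRS7 at 0.58 and IDH3B at -0.56 for neonatal MCFA. For maternal MCFA, MOS was at 1.75, INS at -2.85, F2 at -0.98, PCDH7 at 1.77 and SLC4A4 at 1.12. For neonatal β-glucan in day 1 ileum with those arms, ECI2 was at -0.57, SELENOT at -0.14, SLC11A1 at 1.14, FCGR2B at 1.00, KIR2DL1 at 1.23 and MYOG at 1.06. NLN was at 0.83, PDE4A at 0.37, CNPY3 at 0.75, ADRB1 at 0.82, GATA2 at 0.46 and TP23 at 0.46 there. With normexp in day 31 colon, CLN3 was at -0.18, NAGS at -0.21 and KLF16 at -0.28 for maternal GOS. For age in jejunum controls, FABP2 was at 0.10 with slides 6 and 7 left out and at 0.09 with doubted arrays left out. Within scan day 1, where the day 31 arrays are those of slide 6, IFIT1 was at -0.58, CD8A at -0.05, CCL5 at -0.06 and CD2 at -0.62.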

Other observations

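In the day 31 colon the lysozyme gene LYZ fell into separate ranges, with 2 controls at 2.56 and 1.81 and the others from -3.29 to -1.93. The GOS neonatal arm had 4 arrays from 1.16 to 3.16 and 4 from -2.71 to -1.57, and the GOS maternal arm lay from 1.41 to 2.98.

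IFIT3 on the 4 maternal GOS arrays of the day 31 colon ran from -5.37 to -2.53, the controls from -1.62 to 0.29 and the neonatal arm from -1.94 to 0.67. The age rise of IFIT3 in colon controls was 5.58 ± 0.52.

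The mean level of the features that fell under neonatal β-glucan in the day 1 ileum also varied with slide elsewhere. It was -3.16 on slide 19, -4.24 on slide 20 and -2.33 on slide 22 (1 array) within the day 1 jejunum MCFA neonatal arm, while the β-glucan neonatal array on slide 22 was at -4.17. It was -3.94 on slide 3, -3.43 on slide 22 and -3.2 on slide 4 in the day 1 colon GOS neonatal arm. Within the day 1 jejunum controls it was -3 on slide 1 and -4.13 on slide 2. On slide 22 the MCFA and GOS arrays had 40.37% and 43.04% of spots well above background, against 67.52% on the β-glucan array.

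FABP6, a bile acid carrier of the ileum, rose with age in control ileum (2.98 ± 0.32) and, without slides 6 and 7, in control jejunum (6.49 ± 1.67). In the colon the bile acid transporter SLC10A2 fell with age, at least 4.34-fold, while in the ileum it rose by 3.71 ± 0.68.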
